A study of Mus musculus with 70 samples.

How the data were processed

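The series profiled RNA from the cerebral cortex and the striatum of mice by short-read sequencing. The series' design text gives postnatal days 21 to 23 for the hypothyroid and knockout mice and male sex for the hypothyroid mice. The age of WT and WTa mice and the sex of the other groups are not given in the sources used here. There were 5 conditions, with 7 libraries in each of the 10 groups of tissue and condition and 70 libraries in all. WT denotes untreated wild-type mice. MMI denotes wild-type mice made hypothyroid through the dams' drinking water, which held 0.02% methimazole, a blocker of thyroid hormone synthesis, and 1% potassium perchlorate, a blocker of iodide uptake, from embryonic day 9 to postnatal day 21. MctDio KO denotes a double-knockout line lacking Dio2, which encodes the deiodinase that makes T3 from T4 in brain. MctOatp KO denotes a double-knockout line lacking Slco1c1, which encodes the T4 transporter OATP1C1. WTa denotes the wild-type mice labelled for that second line, and they served as its controls.

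Per the labels, libraries were made from 500 ng of RNA with an unstranded kit and read as single 75-nt reads. The authors named CASAVA, FastQC, Bowtie, TopHat, HTSeq and edgeR, with the mouse build GRCm38. Their versions and settings are not given in the sources used here. The deposited values are raw read counts per gene, with no normalization, in 38293 gene lines and 5 closing lines for reads given to no gene. Gene symbols and positions came from GENCODE release M21, which held 36345 of the identifiers. The other 1948 carried neither a symbol nor a position and were tested under their identifiers. Because reads were unstranded, counts of overlapping genes on opposite strands cannot be separated. Near-identical gene copies share reads, and counts cover each copy only as far as reads mapped to it alone.

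Counts assigned to genes ranged from 7802957 to 22485839 per library. Precision was judged from the spread of the 7 libraries of a group, since counting error is only part of it. The biological coefficient of variation was 0.147 in cortex and 0.109 in striatum. No library repeated another: over 210 pairs within groups, the lowest chi-square per degree of freedom was 2.21, against a value near 1 for repeated sequencing of the same library. That comparison used genes with at least 10 counts.

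Within each tissue, all 35 libraries were fitted together with edgeR 4.0.16 in R 4.3.3, using TMM scaling, filterByExpr and robust quasi-likelihood F tests. This tested 16198 genes in cortex and 16267 in striatum. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a comparison are said to be called. There were 7 planned comparisons within a tissue: the 3 models against their controls, WTa against WT, MctDio KO against MMI, and the change in MctOatp KO minus the change in MMI or in MctDio KO. There were 3 comparisons of the change in striatum with the change in cortex, fitted over all 70 libraries and 16814 genes. Log2 CPM of single libraries, outside voom, use a prior count of 2. Log2 changes are those of the edgeR fit, at its own default prior count. They are given with standard errors, computed as the size of the change divided by the square root of F. Normalised read counts are edgeR's CPM with TMM scaling, given as mean ± SD over 7 libraries.

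All 33 gene lists were written from textbook knowledge before the data were examined, as were the comparisons, the tests and most of the other settings tried. A list of cell-type markers covered each of the main cell types of the dissected tissue and of blood, choroid plexus and neighbouring regions. Each list was tested in each main comparison with camera of limma 3.58.1, on voom log2 CPM with the correlation between genes preset to 0.01. The 198 p-values were adjusted together, and those of WTa against WT separately. Camera compares a list with all other genes. As alternatives, the correlation was estimated for each list, and fry tested whether the members moved on balance one way. Counts of called members are given over all genes and, beside them, adjusted over the list alone. Some genes belong to several lists: Aldh1a1 is on the thyroid hormone and retinoid lists, for example. The list of sex-linked transcripts was included as a check of the samples.

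The rule for naming genes was fixed before the data were examined. It took Dio2, Slco1c1 and Dio3 in every comparison. Some genes it names are not reported here. It took the 8 largest rises and 8 largest falls per main comparison among called genes with a mean of at least 2 CPM and at least 6 of 7 libraries beyond the control mean, without provisional names. It took up to 4 members of each list with the smallest p, and the 3 largest rises and falls in the other comparisons. Wdfy1 is named under it. Nnt, Rps3a2, Gm5148, Ttr, Xist and Ddx3y were named after their values were seen.

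Calls made in both of a pair of models were compared with the number expected from independent calls. The MMI and MctDio KO comparisons share the WT libraries, which makes their changes correlate without any shared biology. This was checked with 10 random splits of the WT libraries between the comparisons, and 20 simulated draws of unchanged groups set against the real WT libraries. The simulation was corrected after its first output had been seen, so that both simulated groups drew from the same gene means. Genes within 10 Mb of a targeted gene were tested for an excess of calls with Fisher's exact test, two-sided, in 24 tests adjusted together, and a scan covered 2120 windows over all chromosomes.

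The number in a sample's title is shared by the cortex and the striatum of a condition and is read here as the same animal. Deviations from the group mean, correlated across genes, exceeded 0.1 for 26 of 35 such pairs, with a median r of 0.215, and the own number was highest of 7 in 17 of 35. In MctOatp KO, with group means that include the libraries that stand apart, the own number was highest for 0 of 7, with r from -0.876 to 0.215. Without numbers 1 and 7, a comparison added after the data were seen, it was highest for 4 of 5, with r from 0.137 to 0.607. Genes are not independent replicates, so no p is attached. Across conditions the numbers did not, as a rule, pair libraries: 13 of 29 pairs exceeded 0.1 in cortex and 9 of 29 in striatum. Number 1 was an exception among WT, MMI and MctDio KO, with r from 0.204 to 0.289 in cortex and from 0.199 to 0.535 in striatum. It also had the highest share of alignments that were not unique in each of these groups. This was picked out after the values were seen, and its cause was not tested. Fits with animal or number as a block were among the other settings.

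The other settings chosen beforehand also covered DESeq2 1.42.0 (size factors in the same fit, and its Wald test), limma voom with quality weights, no filter on low counts, a change of at least 1.5-fold, and fits of only the 2 groups compared. After the data were examined, 3 libraries were seen to stand apart: those labelled cortex MctOatp KO 1, cortex MctOatp KO 7 and striatum MctOatp KO 7. All were kept in the main results as labelled, and leaving them out, together or in turn, was added as an alternative chosen after seeing the data. The pipeline was tested on simulated data with 200 changed genes. Of 50 genes changed 1.5-fold, 64% were called in cortex, 82% in striatum and 60% for a tissue difference. At 2-fold these were 94%, 100% and 94%. Among the genes left unchanged in these comparisons, 2 were called in cortex, 11 in striatum and 3 for the tissue difference, and at most 1 gene was called in a simulated comparison with no effect. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.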

Results

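RNA was sequenced from the cerebral cortex and striatum of 5 groups of mice, with 7 libraries per group and tissue. The groups were untreated wild types (WT), hypothyroid wild types (MMI), a double-knockout line lacking Dio2 (MctDio KO), a double-knockout line lacking Slco1c1 (MctOatp KO), and the wild types labelled for that last line (WTa). Counts assigned to genes ranged from 7802957 to 22485839 per library in cortex and from 8983668 to 19464492 in striatum. Among 431 genes that differed at least 4-fold between the tissues in the control libraries, each library was placed between the mean cortex control at 0 and the mean striatum control at 1. The library labelled cortex MctOatp KO 7 lay at 0.93, and the other cortex libraries lay from -0.13 to 0.12. The library labelled striatum MctOatp KO 7 lay at -0.05, and the other striatum libraries lay from 0.81 to 1.09. In the library labelled cortex MctOatp KO 1, 39.7% of alignments were not unique, against 27.8% to 29.0% in the other 6. All 3 libraries were kept as labelled, and values without them are given for many, though not all, of the results that differ.

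**Figure D1:**
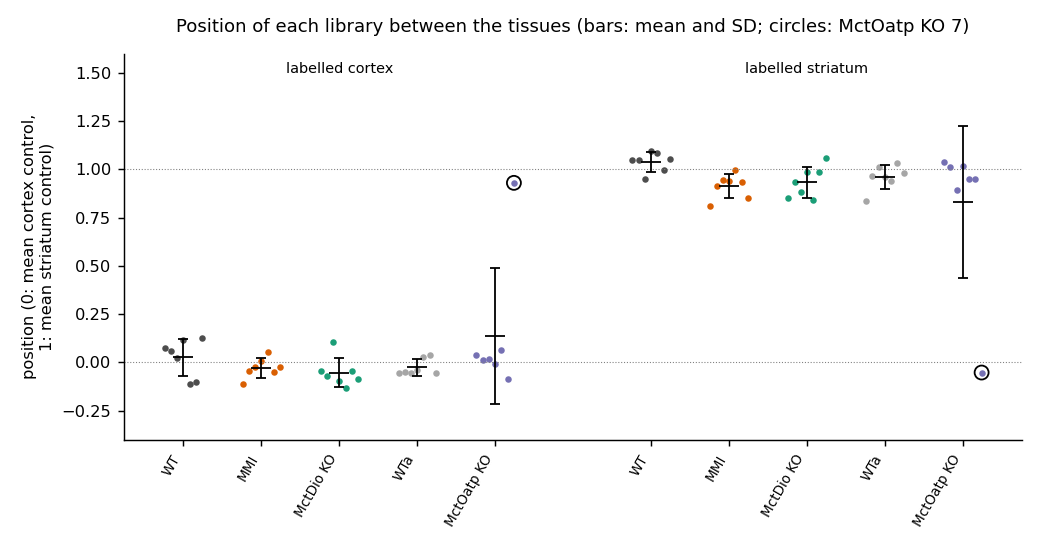
Position of each library (points, vertical axis, no unit) between the mean cortex control at 0 and the mean striatum control at 1, by group (horizontal axis), with bars for mean and SD of 7 libraries. The circled libraries labelled MctOatp KO 7 lie at 0.93 among the cortex libraries and at -0.05 among the striatum libraries.

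Dio2 and Slco1c1 transcripts were lower in the lines that lack these genes, and both genes rose in hypothyroid cortex. Dio2 (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438, GRCm38), whose product makes T3 from T4, fell from 176 ± 20.6 to 6.23 ± 1.2 CPM (SD, n = 7) in cortex of MctDio KO (log2 change -4.82 ± 0.13 SE, adjusted p = 5.68e-25). In striatum of that line Dio2 fell from 110 ± 15.9 to 5.16 ± 0.998 CPM (-4.44 ± 0.16, adjusted p = 2.39e-21). Slco1c1 (ENSMUSG00000030235, chromosome 6, 141524368 to 141570177), the gene of OATP1C1, fell in MctOatp KO but kept many reads. It went from 85 ± 8.25 to 43.2 ± 8.37 CPM in cortex (-0.97 ± 0.11, adjusted p = 1.09e-07) and from 85.2 ± 4.56 to 45.7 ± 3.47 CPM in striatum (-0.90 ± 0.09, adjusted p = 5.29e-10). The counts per gene do not show which part of the transcript the remaining reads came from.

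In MMI, Dio2 rose to 320 ± 35 CPM in cortex (0.86 ± 0.11, adjusted p = 2.64e-07) and to 210 ± 18.6 CPM in striatum (0.93 ± 0.12, adjusted p = 4.54e-07). Slco1c1 rose in cortex of MMI (0.41 ± 0.11, adjusted p = 0.00624) and measured 0.17 ± 0.08 in striatum (adjusted p = 0.103). In MctOatp KO, Dio2 rose in striatum from 136 ± 13.3 to 215 ± 65.3 CPM (0.66 ± 0.12, adjusted p = 0.000171), and in cortex its change of 0.17 ± 0.11 did not pass (adjusted p = 0.317). Dio3 (ENSMUSG00000075707, chromosome 12, 110279068 to 110281097), whose product inactivates thyroid hormone, was scarce, at 2.37 ± 0.771 CPM in cortex and 0.718 ± 0.215 CPM in striatum of WT. None of its main comparisons passed, with changes from -0.99 ± 0.56 to -0.55 ± 0.40. Its change in striatum of MctOatp KO was -0.88 ± 0.52 as labelled and -2.76 (adjusted p = 1.19e-05) without the library labelled striatum MctOatp KO 7.

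**Figure D2:**
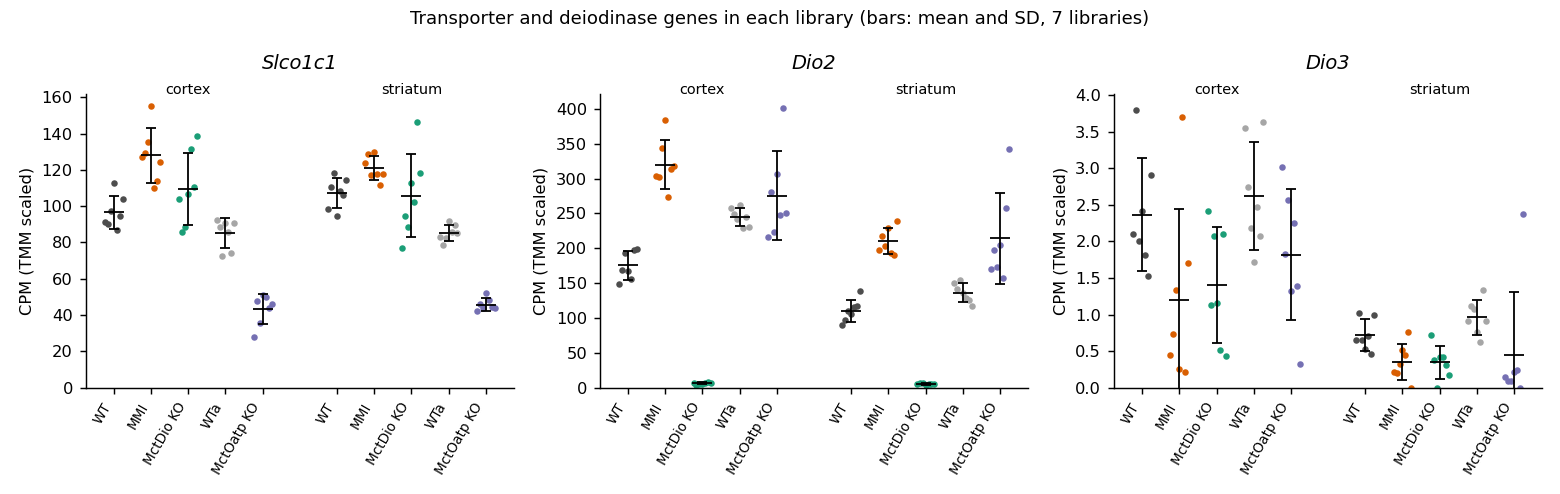
Normalised read count (CPM, TMM scaled, vertical axis) of Slco1c1, Dio2 and Dio3 in each library (points) by group, with bars for mean and SD of 7 libraries. Dio2 averages 6.23 CPM in cortex of MctDio KO against 176 CPM in WT, and Slco1c1 averages 43.2 CPM in cortex of MctOatp KO against 85 CPM in WTa.

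The largest falls in hypothyroid cortex among the genes named by the rule were those of Pvalb, Aldh1a1 and Robo3. Pvalb, the calcium-binding protein of fast-spiking interneurons, fell from 58.1 ± 8.96 CPM in WT to 4.16 ± 0.963 CPM in MMI (-3.79 ± 0.30). Aldh1a1, an enzyme of retinoic acid synthesis, fell from 54.4 ± 3.61 to 4.12 ± 0.782 CPM (-3.72 ± 0.11). Robo3, an axon guidance receptor, fell by 3.06 ± 0.26, and Syt2, a synaptotagmin of fast synapses, fell by 2.996 ± 0.27. The potassium channel gene Kcng4 fell by 2.92 ± 0.20 and its glial relative Kcnj10 fell by 2.67 ± 0.17. Adamtsl5 and Scn4b, the gene of a sodium channel subunit, completed the 8 largest falls, at -2.94 ± 0.24 and -2.86 ± 0.75. The largest rise was that of Ly75, an endocytic receptor, from 2.47 ± 0.74 to 13 ± 2.42 CPM (2.37 ± 0.19). Other large rises were those of Ifi44 (2.19 ± 0.33), Prss56 (1.99 ± 0.43), Myoc (1.84 ± 0.25), Igfbp3 (1.82 ± 0.15), Vegfd (1.80 ± 0.21) and Colq (1.79 ± 0.20). For each of these 15 genes all 7 MMI libraries lay beyond the WT mean, and adjusted p ran from 1.79e-23 for Aldh1a1 to 0.00516 for Scn4b.

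In striatum the same comparison gave the largest fall for Robo3, from 25.9 ± 6.85 to 0.587 ± 0.174 CPM (-5.45 ± 0.60). Prlr, the prolactin receptor gene and a choroid plexus marker, fell from 22.8 ± 7.84 to 1.22 ± 0.665 CPM (-4.16 ± 0.55). Cd72, an inhibitory receptor of B cells (-4.12 ± 0.25), Aldh1a1 (-3.94 ± 0.10), Gpr139 (-3.66 ± 0.39), Cyp2s1 (-3.15 ± 0.18), Impg1 (-3.13 ± 0.28) and Adamtsl4 (-2.96 ± 0.19) also fell. Slco2a1, the prostaglandin transporter, rose from 0.685 ± 0.381 to 4.31 ± 0.649 CPM (2.65 ± 0.30). Ly75 (2.35 ± 0.20), the diacylglycerol kinase gene Dgkk (2.25 ± 0.27), Ifi44 (2.21 ± 0.22), the sodium channel gene Scn9a (2.12 ± 0.28), Rasgrp4 (2.10 ± 0.22), Ddx60 (2.03 ± 0.34) and Tnxb (1.96 ± 0.19) rose too. Adjusted p for these 16 genes ran from 4.09e-26 for Aldh1a1 to 1.84e-05 for Ddx60, again with all 7 MMI libraries beyond the WT mean. In all, 1773 genes were higher and 1577 lower in cortex, and 2602 were higher and 2736 lower in striatum. Without the 3 libraries that stand apart, none of them WT or MMI, cortex gave 3269 and 3290. Without cortex MctOatp KO 1 alone its total of 3350 became 5463. Without all 3 the totals were 6559 in cortex and 6325 in striatum. Counts of called genes or list members as labelled therefore do not show which tissue changed more.

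Known targets of thyroid hormone moved as groups in MMI. Of 31 measured genes listed as induced by thyroid hormone, 21 were lower and 6 higher in cortex (22 and 7 adjusted over the list alone). Of 30 in striatum 22 were lower and 3 higher (22 and 3 adjusted over the list alone). The list fell in both tissues (adjusted p = 8.47e-17 and 1.43e-13; 5.31e-07 and 3.93e-06 with an estimated correlation). Hr, a corepressor, fell by 2.53 ± 0.12 in cortex, and the neurofilament genes Nefm and Nefh fell by 2.10 ± 0.08 and 1.55 ± 0.08. In striatum Sema7a, a semaphorin, fell by 2.22 ± 0.14 and Abcd2, a peroxisomal fatty acid transporter, by 1.34 ± 0.07. Against the name of the list, Reln, a secreted guide of neuronal positioning, and Slc1a3, a glutamate transporter, rose in cortex (0.59 ± 0.10 and 0.69 ± 0.10). Of 14 genes listed as repressed by thyroid hormone, 11 were higher in cortex and 12 in striatum (12 and 12 adjusted over the list alone). That list rose (adjusted p = 1.47e-10 and 3.06e-09; 1.73e-06 and 1.67e-05 with an estimated correlation), with Gpc3, a glypican, at 1.66 ± 0.18 and Mamdc2 at 1.69 ± 0.19 in cortex, and the collagen VI genes Col6a1 and Col6a2 at 1.32 ± 0.13 and 1.13 ± 0.12 in striatum.

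**Figure D3:**
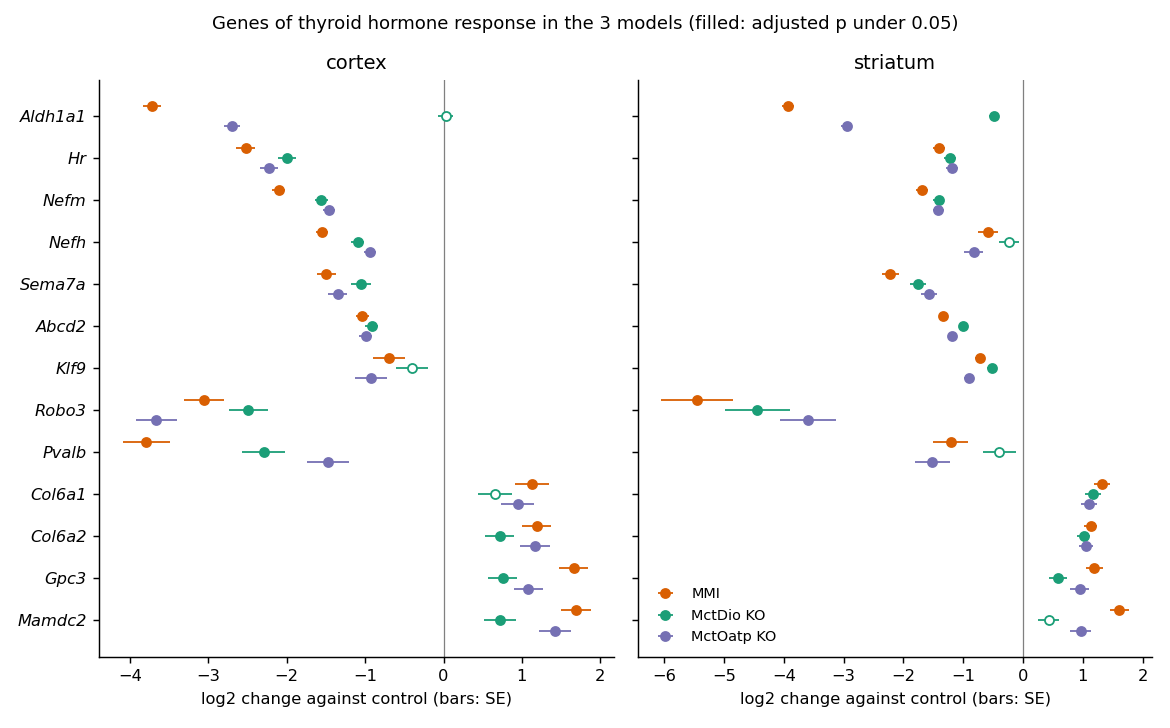
Log2 change against control (horizontal axis) with SE bars for 13 genes (vertical axis) in MMI, MctDio KO and MctOatp KO, by tissue; filled points have an adjusted p under 0.05. Aldh1a1 lies at -3.72 in cortex of MMI and at -2.70 in MctOatp KO, whereas in MctDio KO it lies near 0.

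Fast-spiking interneuron and perineuronal net genes fell in cortex of MMI. There, 10 of 21 were lower and 1 higher (11 and 1 adjusted over the list alone; adjusted p = 1.09e-12, and 0.0023 with an estimated correlation). Hapln4, a link protein of perineuronal nets, measured -2.39 ± 0.14 and Cplx1, a complexin, -0.90 ± 0.06. In striatum 11 of 21 were lower (12 adjusted over the list alone; adjusted p = 0.000287, and 0.207 with an estimated correlation). Lynx1, a modulator of nicotinic receptors, fell there by 1.53 ± 0.07, while Hapln1 rose (0.67 ± 0.09). Voltage-gated channel genes followed, with 15 of 29 lower in cortex and 17 in striatum (15 and 19 adjusted over the list alone; adjusted p = 2.27e-08 and 1.56e-07, and 0.102 and 0.121 with an estimated correlation). Among them Kcna1, a potassium channel gene of axons, fell by 1.33 ± 0.11 in cortex and by 1.08 ± 0.08 in striatum. Cholesterol synthesis and uptake genes were lower for 17 of 25 in cortex and 20 in striatum (19 and 20 adjusted over the list alone; adjusted p = 2.62e-12 and 1.11e-09, and 0.000609 and 0.149 with an estimated correlation). Insig1, a regulator of sterol synthesis, measured -0.72 ± 0.12 and -0.81 ± 0.09. Nuclear-encoded respiratory chain genes were lower for 36 of 37 in striatum and 9 of 37 in cortex (36 and 9 adjusted over the list alone; adjusted p = 2.76e-20 and 9.18e-07, and 0.0271 and 0.622 with an estimated correlation). In striatum Ndufa1 fell by 0.75 ± 0.07 and Cox5a by 0.57 ± 0.05. In cortex as well, 36 of 37 were lower without the 3 libraries that stand apart. The striatum libraries of MMI also differed from those of WT in reads outside genes (9.28% to 10.4% against 8% to 8.76%) and in ambiguous reads (1.55% to 1.59% against 1.63% to 1.65%).

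Glial and blood cell markers also differed between MMI and WT. Myelin and mature oligodendrocyte genes were lower for 20 of 26 in cortex and 8 of 26 in striatum (23 and 8 adjusted over the list alone; adjusted p = 1.5e-11 and 0.00618, and 0.331 and 0.741 with an estimated correlation). Aspa fell by 1.42 ± 0.27 in cortex and Klk6, an oligodendrocyte protease, by 1.51 ± 0.25 in striatum. Microglia genes were higher for 7 of 17 in cortex and 13 of 17 in striatum (9 and 14 adjusted over the list alone; adjusted p = 0.000106 and 1.73e-06, and 0.361 and 0.246 with an estimated correlation). Cx3cr1, the fractalkine receptor gene, rose by 0.37 ± 0.09 and 0.40 ± 0.07. All 7 erythroid genes were lower in cortex and all 6 in striatum (7 and 6 adjusted over the list alone; adjusted p = 5.71e-06 and 0.000138, and 0.129 and 0.208 with an estimated correlation). The globin gene Hbb-bs, a marker of blood left in the tissue, fell by 1.45 ± 0.29 and 1.58 ± 0.21. Extracellular matrix genes were higher for 13 of 23 in cortex and 9 in striatum (13 and 9 adjusted over the list alone; adjusted p = 0.000445 and 0.0032, and 0.287 and 0.179 with an estimated correlation). The collagen gene Col11a1 fell instead by 1.39 ± 0.14 in cortex. Astrocyte genes were split: Ntsr2 fell by 0.85 ± 0.09 in cortex, Slc1a3 rose, and 4 of 18 were higher and 5 lower (4 and 5 adjusted over the list alone; adjusted p = 0.0832). In striatum 2 of 18 were higher and 6 lower (2 and 6 adjusted over the list alone; adjusted p = 0.0288, and 0.63 with an estimated correlation).

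Smaller groups moved in MMI as well, and none of the list calls given next held with an estimated correlation. Immediate early genes were lower for 5 of 22 in each tissue (6 in cortex and 5 in striatum adjusted over the list alone; adjusted p = 0.000321 and 0.00764, and 0.454 and 0.63 with an estimated correlation). Arc, a gene of synaptic plasticity, measured -1.72 ± 0.33 in cortex. Synaptic genes were lower for 6 of 27 in cortex and 12 in striatum (6 and 12 adjusted over the list alone; adjusted p = 0.0127 and 0.00278, and 0.57 and 0.454 with an estimated correlation). Nrgn, a calmodulin-binding protein of dendrites, measured -0.91 ± 0.18 and -2.21 ± 0.21. Medium spiny neuron genes were lower for 9 of 25 in striatum (10 adjusted over the list alone; adjusted p = 0.015, and 0.769 with an estimated correlation). Rasd2, a striatal GTPase, was among them (-1.47 ± 0.27), and 21 of 25 were lower without the 3 libraries that stand apart. In cortex 2 of 25 were lower (2 adjusted over the list alone; adjusted p = 0.019, and 0.769 with an estimated correlation). Heat shock genes were lower for 4 of 15 in cortex and 10 of 15 in striatum (4 and 10 adjusted over the list alone; adjusted p = 0.0103 and 0.0042, and 0.421 and 0.441 with an estimated correlation). Hsph1, a chaperone gene, measured -0.71 ± 0.10 and -0.61 ± 0.12. Endothelial genes were higher for 7 of 18 in cortex and 6 in striatum (7 and 6 adjusted over the list alone; adjusted p = 0.00156 and 0.0204, and 0.454 and 0.622 with an estimated correlation). Kdr, the VEGF receptor gene, rose by 0.72 ± 0.15 and 0.67 ± 0.13. Mural and leptomeningeal genes were higher for 9 of 18 in cortex (10 adjusted over the list alone; adjusted p = 0.000445, and 0.287 with an estimated correlation). In striatum choroid plexus and ependyma genes were lower for 6 of 15 (6 adjusted over the list alone; adjusted p = 0.0103, and 0.672 with an estimated correlation). Ttr, the most abundant choroid plexus transcript, measured -0.74 ± 0.61 (adjusted p = 0.375).

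In the same comparison ribosomal protein genes were higher for 14 of 39 in striatum (14 adjusted over the list alone; adjusted p = 0.00243, and 0.65 with an estimated correlation). Oligodendrocyte precursor genes were higher for 7 of 16 in striatum (8 adjusted over the list alone; adjusted p = 0.00764, and 0.633 with an estimated correlation), with Pdgfra, a receptor gene of these cells, at 0.42 ± 0.09. Mitochondrially encoded genes were lower for 5 of 7 in striatum (5 adjusted over the list alone; adjusted p = 0.0218, and 0.63 with an estimated correlation), and immature neuron genes higher for 5 of 20 in cortex (5 adjusted over the list alone; adjusted p = 0.0345, and 0.454 with an estimated correlation).

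MctDio KO gave fewer changes than hypothyroidism in the same fit. Apart from the targeted genes and Rps3a1, the largest falls in cortex of MctDio KO were those of Robo3, from 79.8 ± 21.2 to 14.2 ± 3.09 CPM (-2.49 ± 0.25), Syt2 (-2.32 ± 0.26), Pvalb (-2.29 ± 0.27), Tmem215 (-2.10 ± 0.25) and Adamtsl5 (-2.09 ± 0.22). Aldh1a1 stayed at 55.6 ± 9.59 CPM, against 54.4 ± 3.61 CPM in WT. Rises included Rtp1, an odorant receptor chaperone (2.36 ± 0.30), Colq (1.31 ± 0.21), Cybrd1, a ferric reductase (1.2495 ± 0.17), Esr1, the estrogen receptor gene (1.20 ± 0.26), Aldh3b2 (1.19 ± 0.24), Mc4r, a melanocortin receptor gene (1.18 ± 0.19), and Vegfd (1.13 ± 0.21). Adjusted p for these 12 genes ran from 8.01e-09 for Robo3 to 0.00205 for Esr1, with all 7 libraries beyond the WT mean except for Vegfd, with 6. Counts of the near-identical ribosomal protein genes Rps3a1 and Rps3a3 moved in opposite directions: Rps3a1 went from 24.2 ± 1.57 to 0.746 ± 0.109 CPM (-5.02 ± 0.34) and Rps3a3 from 0.249 ± 0.137 to 37.6 ± 3.89 CPM (7.38 ± 0.21). These copies share reads, so the pair cannot be read gene by gene.

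In striatum of MctDio KO the falls, apart from those of the targeted genes and Rps3a1, were led by Robo3 (-4.45 ± 0.55), Cd72 (-3.84 ± 0.24), Gpr139 (-3.32 ± 0.38), Cyp2s1 (-2.72 ± 0.17) and Impg1 (-2.45 ± 0.26), with Rps3a1 at -5.17 ± 0.13 and Rps3a3 at 7.95 ± 0.22. Rises were led by Scn9a, from 5.36 ± 1.23 to 19.1 ± 7.72 CPM (1.85 ± 0.28), Dgkk (1.65 ± 0.28), Baiap3 (1.63 ± 0.18), Syt10 (1.54 ± 0.20), AW551984 (1.53 ± 0.25), the MHC class II chain gene Cd74 (1.51 ± 0.28) and Gpr101 (1.43 ± 0.20). Aldh1a1 fell by 0.49 ± 0.08 (adjusted p = 5.66e-05). Adjusted p for the other genes named here ran up to 0.000217 for Cd74, and all 7 libraries lay beyond the WT mean for each. In cortex 543 genes were higher and 678 lower, and in striatum 1151 and 1276. The cortex total of 1221 became 2610 without cortex MctOatp KO 1 and 1914 without the library labelled cortex MctOatp KO 7. Without the 3 libraries that stand apart, the cortex counts were 1827 and 1933. The totals were then 3760 in cortex and 3528 in striatum. Counts of called genes or list members as labelled therefore do not show which tissue changed more.

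Thyroid hormone target lists moved in MctDio KO in the directions seen in MMI. Induced genes were lower for 18 of 31 in cortex and 18 of 30 in striatum (19 and 20 adjusted over the list alone; adjusted p = 2.17e-16 and 8.4e-16, and 5.43e-07 and 1.12e-06 with an estimated correlation). Examples were Hr (-1.9966 ± 0.11 in cortex), Nefm (-1.56 ± 0.08 and -1.41 ± 0.09) and Sema7a (-1.76 ± 0.14 in striatum). Repressed genes were higher for 6 of 14 in cortex and 8 of 14 in striatum (9 and 9 adjusted over the list alone; adjusted p = 0.00629 and 0.00278, and 0.0278 and 0.0271 with an estimated correlation), with the targeted gene Dio2 among the rest. Fxyd6 rose by 0.93 ± 0.12 in cortex and Col6a2 by 1.01 ± 0.12 in striatum. Interneuron and perineuronal net genes were lower for 10 of 21 in cortex (10 adjusted over the list alone; adjusted p = 1.14e-15, and 0.00062 with an estimated correlation). Hapln4 measured -1.71 ± 0.13. In striatum 5 of 21 were lower (6 adjusted over the list alone; adjusted p = 0.000438, and 0.228 with an estimated correlation). Cholesterol genes were lower for 7 of 25 in cortex and 18 in striatum (10 and 20 adjusted over the list alone; adjusted p = 9.08e-08 and 2.72e-13, and 0.00913 and 0.0836 with an estimated correlation). Cyp51, a synthesis enzyme gene, fell by 0.57 ± 0.09 in striatum.

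Myelin genes fell in cortex of MctDio KO, where 18 of 26 were lower and 5 of 26 were in striatum (25 and 5 adjusted over the list alone; adjusted p = 3.57e-21 and 1.12e-05, and 0.121 and 0.633 with an estimated correlation). Opalin fell by 1.38 ± 0.23 and Mog by 1.14 ± 0.25 in cortex. Channel genes were lower for 11 of 29 in cortex and 12 in striatum (15 and 16 adjusted over the list alone; adjusted p = 1.2e-08 and 1.56e-07, and 0.0946 and 0.121 with an estimated correlation), including Kcnab3 (-1.38 ± 0.15 in cortex). Respiratory chain genes were lower for 1 of 37 in cortex and 15 in striatum (1 and 20 adjusted over the list alone; adjusted p = 4.69e-05 and 2.65e-10, and 0.672 and 0.169 with an estimated correlation). Microglia genes were higher for 1 of 17 in cortex and 10 in striatum (7 and 13 adjusted over the list alone; adjusted p = 0.00152 and 7.93e-05, and 0.476 and 0.385 with an estimated correlation). The microglial gene Fcrls fell instead, by 1.03 ± 0.14 and 1.09 ± 0.11. Glucocorticoid responsive genes were higher for 3 of 15 in cortex and 4 in striatum (5 and 9 adjusted over the list alone; adjusted p = 0.00147 and 0.00764, and 0.161 and 0.454 with an estimated correlation). Hif3a, a hypoxia-inducible factor gene, rose by 0.93 ± 0.22 and 0.96 ± 0.24. The rise of this list was not particular to MctDio KO, since WT had the lowest list mean of the 5 groups in each tissue. In cortex the means were 4.44 ± 0.11 log2 CPM in WT, 4.76 ± 0.11 in MMI and 4.78 ± 0.12 in MctDio KO (SD, n = 7). In striatum they were 4.39 ± 0.09 in WT, 4.705 ± 0.09 in MMI and 4.75 ± 0.20 in MctDio KO. Medium spiny neuron genes were lower for 1 of 25 in cortex and 5 in striatum (0 and 9 adjusted over the list alone; adjusted p = 0.0142 and 0.0134, and 0.765 and 0.769 with an estimated correlation). Ribosomal protein genes were higher for 2 of 38 in cortex and 9 of 39 in striatum (1 and 15 adjusted over the list alone; adjusted p = 0.0146 and 6.85e-06, and 0.769 and 0.454 with an estimated correlation).

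A few more lists were called in MctDio KO on 4 or fewer members. In cortex choroid plexus genes were lower for 1 of 13 and immature neuron genes higher for 1 of 20 (1 and 1 adjusted over the list alone; adjusted p = 0.0108 and 0.0272, and 0.65 and 0.441 with an estimated correlation). In striatum endothelial genes were lower for 3 of 18 and synaptic genes for 4 of 27 (5 and 4 adjusted over the list alone; adjusted p = 0.0192 and 0.0324, and 0.622 and 0.65 with an estimated correlation).

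MctOatp KO lowered many of the genes that fell in hypothyroid cortex. Robo3 fell from 106 ± 20.7 CPM in WTa to 8.16 ± 4.34 CPM in MctOatp KO (-3.67 ± 0.26), Aldh1a1 from 61.8 ± 4.69 to 9.62 ± 1.39 CPM (-2.70 ± 0.11) and Hr from 85.3 ± 7.87 to 18.1 ± 4.11 CPM (-2.22 ± 0.11). Etnppl, an enzyme of phosphoethanolamine breakdown (-2.65 ± 0.34), Npnt, a matrix protein gene (-2.29 ± 0.13), Kcng4 (-2.28 ± 0.19) and Ky (-2.21 ± 0.25) fell as well, with adjusted p from 7.03e-20 for Aldh1a1 to 1.18e-06 for Etnppl and all 7 libraries below the WTa mean. The largest rises in cortex rested in part on the libraries that stand apart. Of Jsrp1 (2.19 ± 0.35), Clic6 (2.09 ± 0.71), Dach1 (2.08 ± 0.46), Rec8 (2.04 ± 0.36), Folr1 (2.01 ± 0.65), Gpr6 (1.996 ± 0.49), Ano2 (1.99 ± 0.47) and Gpr101 (1.89 ± 0.55), only Jsrp1 (1.38, adjusted p = 2.45e-06), Rec8 (1.69, adjusted p = 0.00037) and Ano2 (1.03, adjusted p = 0.0224) passed without them. Rec8 was also lower in the WTa controls than in WT (-1.59 ± 0.37). In all, 1132 genes were higher and 948 lower in cortex, against 1664 and 1905 without the 3 libraries. A fit of only the 2 groups compared, with all libraries as labelled, gave 270 and 310, and these included 27.8% of the main calls. Leaving out cortex MctOatp KO 1 alone gave 3160 in place of 2080.

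In striatum of MctOatp KO the largest falls were those of Robo3, from 45 ± 7.7 to 3.35 ± 6.62 CPM (-3.60 ± 0.47), Cd72 (-3.57 ± 0.25), Cyp2s1 (-3.30 ± 0.18), Impg1 (-2.96 ± 0.27), Aldh1a1 (-2.95 ± 0.09), Tnnt1, a troponin gene (-2.80 ± 0.40), and Kcng4 (-2.47 ± 0.32). Without the library labelled striatum MctOatp KO 7, Robo3 measured -5.70. Rec8, a meiotic cohesin gene (1.85 ± 0.32), Scn9a (1.79 ± 0.28), Aloxe3 (1.504 ± 0.30), Trhr, the receptor gene of thyrotropin-releasing hormone (1.46 ± 0.37), Gpr101 (1.45 ± 0.20) and Pamr1 (1.44 ± 0.19) rose, with adjusted p up to 0.00434 for Trhr. For Rec8 the WTa controls measured -1.004 ± 0.33 against WT (adjusted p = 0.064). Syt17 (1.93 ± 0.46) and Tac2 (1.497 ± 0.50) rose as labelled, and without that library Syt17 measured 0.59 and Tac2 0.28 (adjusted p = 0.603). In all, 1819 genes were higher and 1747 lower, against 1971 and 2127 without the 3 libraries.

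Thyroid hormone induced genes were lower for 18 of 31 in cortex and 21 of 30 in striatum of MctOatp KO (18 and 21 adjusted over the list alone; adjusted p = 5.37e-17 and 7.21e-18, and 5.31e-07 and 5.31e-07 with an estimated correlation). Klf9, a hormone-induced transcription factor, fell by 0.90 ± 0.08 in striatum, and Nefm fell by 1.46 ± 0.08 in cortex. Repressed genes were higher for 10 of 14 in each tissue (10 and 10 adjusted over the list alone; adjusted p = 8.26e-07 and 6.08e-07, and 8.72e-05 and 0.000188 with an estimated correlation). Interneuron and perineuronal net genes were lower for 12 of 21 in cortex and 10 in striatum (12 and 13 adjusted over the list alone; adjusted p = 4.43e-14 and 1.06e-06, and 0.00106 and 0.089 with an estimated correlation). Pvalb fell by 1.47 ± 0.27 in cortex, where it measured -2.29 without the 3 libraries that stand apart, and by 1.52 ± 0.29 in striatum. Cholesterol genes were lower for 6 of 25 in cortex and 22 in striatum (8 and 24 adjusted over the list alone; adjusted p = 3.16e-06 and 2.22e-18, and 0.0271 and 0.0266 with an estimated correlation). The synthesis enzyme genes Dhcr7 and Fdft1 measured -0.46 ± 0.08 in cortex and -0.54 ± 0.05 in striatum.

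Astrocyte genes were lower for 8 of 18 in cortex and 10 in striatum of MctOatp KO (9 and 12 adjusted over the list alone; adjusted p = 2.33e-06 and 2.16e-05, and 0.121 and 0.205 with an estimated correlation). Gjb6, a connexin gene of astrocytes, fell by 0.86 ± 0.12 and Acsbg1 by 0.67 ± 0.09 in cortex. Glucocorticoid responsive genes were lower for 6 of 15 in cortex and 8 in striatum (7 and 10 adjusted over the list alone; adjusted p = 0.000296 and 3.03e-07, and 0.109 and 0.089 with an estimated correlation). In striatum Tsc22d3 measured -0.95 ± 0.10 and Fkbp5, a cochaperone of the glucocorticoid receptor, -0.84 ± 0.10. Immediate early genes were higher for 6 of 22 in cortex and 10 in striatum (10 and 13 adjusted over the list alone; adjusted p = 0.00649 and 0.000991, and 0.63 and 0.495 with an estimated correlation). Egr2 rose by 1.40 ± 0.30 in cortex and Fosb by 1.30 ± 0.25 in striatum. Both lists also differed between the wild-type groups, in the opposite direction. Respiratory chain genes were lower for 26 of 37 in striatum (29 adjusted over the list alone; adjusted p = 2.62e-12, and 0.121 with an estimated correlation) and for 3 in cortex (1 adjusted over the list alone; adjusted p = 0.642), where 27 were lower without the 3 libraries (adjusted p = 5.53e-14, and 0.142 with an estimated correlation). Channel genes were lower for 12 of 29 in cortex and 9 in striatum (14 and 9 adjusted over the list alone; adjusted p = 9.34e-07 and 0.00152, and 0.149 and 0.437 with an estimated correlation). Mitochondrially encoded genes were lower for 7 of 7 in striatum (7 adjusted over the list alone; adjusted p = 0.000547, and 0.382 with an estimated correlation) and 0 of 7 in cortex (0 adjusted over the list alone; adjusted p = 0.0321, and 0.538 with an estimated correlation).

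Myelin genes were lower for 15 of 26 in striatum of MctOatp KO (21 adjusted over the list alone; adjusted p = 4.2e-11, and 0.407 with an estimated correlation). Klk6 measured -1.74 ± 0.26. Oligodendrocyte precursor genes were lower for 7 of 16 in striatum (8 adjusted over the list alone; adjusted p = 0.000533, and 0.476 with an estimated correlation). In cortex no myelin gene was called, and the test placed the list lower (adjusted p = 0.0289, and 0.769 with an estimated correlation) although its median change was 0.074 and its mean 0.069. Without the 3 libraries 22 of 26 were lower in cortex (adjusted p = 4.97e-14, and 0.158 with an estimated correlation). Medium spiny neuron genes were higher for 16 of 25 in cortex as labelled (21 adjusted over the list alone; adjusted p = 0.00762, and 0.738 with an estimated correlation), and without the 3 libraries 0 were higher and 3 lower (adjusted p = 0.626). In striatum 4 of 25 were lower (4 adjusted over the list alone; adjusted p = 0.000689, and 0.723 with an estimated correlation), and 9 without them (adjusted p = 0.23). Choroid plexus genes were higher for 6 of 13 in cortex (11 adjusted over the list alone; adjusted p = 0.000771, and 0.511 with an estimated correlation), with 1 of 13 higher without the 3 libraries. Ribosomal protein genes were higher for 2 of 38 in cortex (1 adjusted over the list alone; adjusted p = 0.00138, and 0.724 with an estimated correlation), against an adjusted p of 0.985 without the 3 libraries. Neurofilament, synaptic and immature neuron lists were called in cortex and not in striatum, and the difference between tissues was not tested. In cortex the list tests gave adjusted p = 0.000438, 0.000296 and 0.00123, and 0.18, 0.331 and 0.179 with an estimated correlation. There 4 of 22 and 5 of 27 were lower and 5 of 20 higher (4, 7 and 9 adjusted over the list alone). Endothelial genes were lower for 3 of 18 in cortex (3 adjusted over the list alone; adjusted p = 0.0135, and 0.612 with an estimated correlation). In striatum microglia genes were higher for 4 of 17, ribosomal protein genes higher for 2 of 39 and choroid plexus genes lower for 1 of 15 (4, 0 and 1 adjusted over the list alone; adjusted p = 0.0475, 0.0451 and 0.0386, and 0.709, 0.746 and 0.724 with an estimated correlation).

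**Figure D4:**
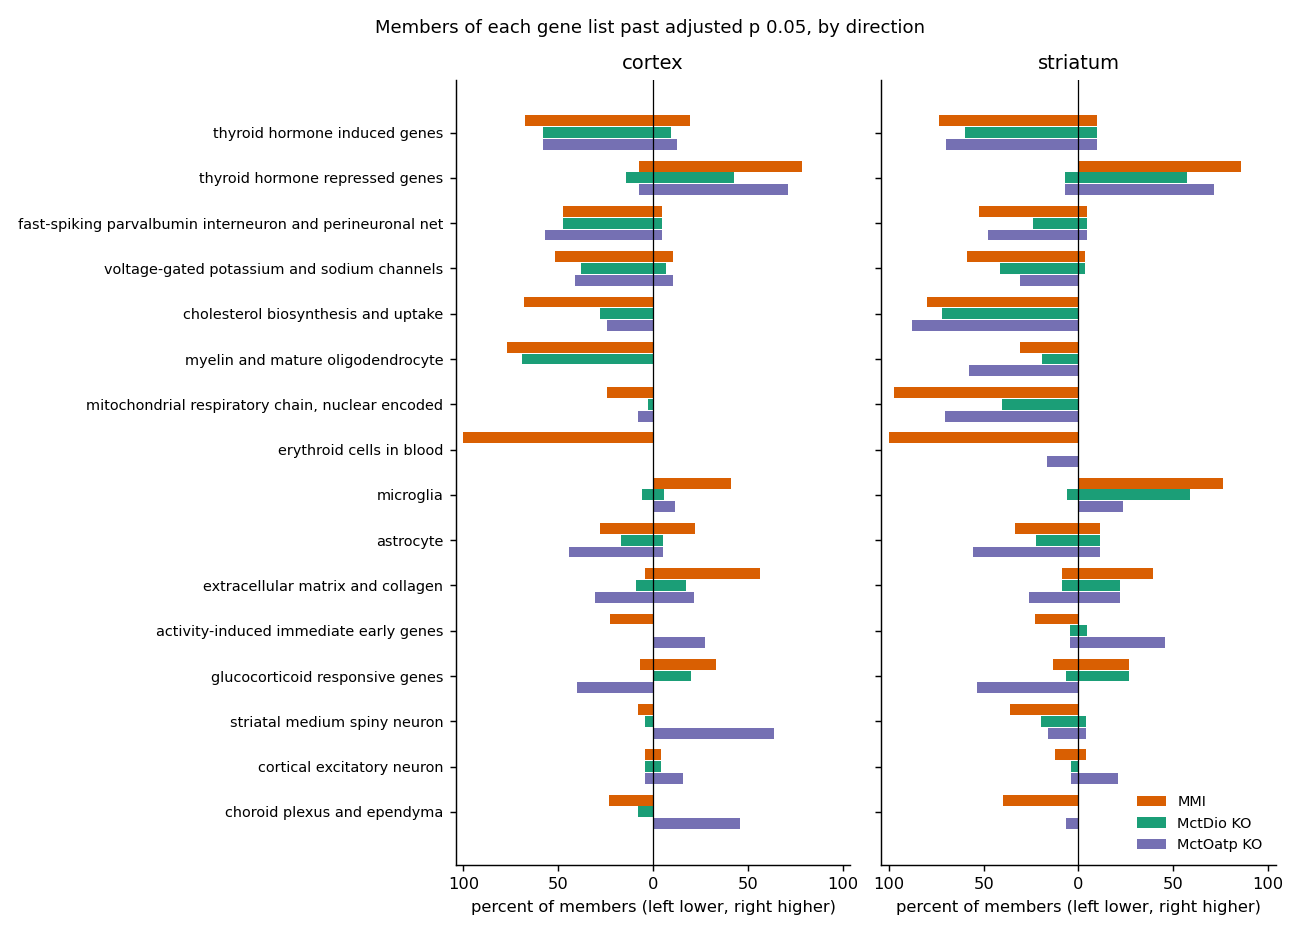
Percent of measured members of 16 gene lists (vertical axis) that were called lower (left) or higher (right, horizontal axis) in MMI, MctDio KO and MctOatp KO, by tissue, with all libraries as labelled. In striatum of MMI 36 of 37 respiratory chain genes were lower; in cortex of MctOatp KO the 16 of 25 medium spiny neuron genes called higher became 0 without the 3 libraries that stand apart.

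The wild-type groups differed from each other. Wdfy1 was higher in WTa than in WT, at 61.6 ± 3.36 against 23.9 ± 2.69 CPM in cortex (1.37 ± 0.11, adjusted p = 6.53e-10) and at 76.8 ± 1.98 against 23.3 ± 2.03 CPM in striatum (1.72 ± 0.09, adjusted p = 2.44e-15). The glucocorticoid responsive genes Fkbp5 and Hif3a were higher in cortex (1.16 ± 0.17 and 1.15 ± 0.22), as were Zbtb16 and Plin4 in striatum (2.46 ± 0.48 and 1.65 ± 0.30). The activity-dependent genes Egr2 and Arc were lower in cortex (-1.48 ± 0.30 and -1.47 ± 0.32), as was Rec8 (-1.59 ± 0.37). In striatum Sstr5, a somatostatin receptor gene (-3.18 ± 0.43), Wfikkn2 (-2.27 ± 0.49) and Sema3b (-1.35 ± 0.35) were lower. Glucocorticoid responsive genes were higher for 5 of 15 in cortex and 8 in striatum (7 and 9 adjusted over the list alone; adjusted p = 2.1e-10 in both, and 0.00803 and 0.0447 with an estimated correlation). Immediate early genes were lower for 8 of 22 in cortex and 11 in striatum (15 and 15 adjusted over the list alone; adjusted p = 5.82e-19 and 1.51e-11, and 0.0447 and 0.165 with an estimated correlation). Dio2 was higher in cortex of WTa (0.48 ± 0.11, adjusted p = 0.0179), and Slco1c1 was lower in its striatum (-0.33 ± 0.08). Endothelial genes were lower for 1 of 18 in cortex and 8 in striatum (6 and 10 adjusted over the list alone; adjusted p = 0.000393 and 0.00103, and 0.892 in both with an estimated correlation). Mural and leptomeningeal genes were lower for 4 of 18 in striatum (7 adjusted over the list alone; adjusted p = 0.00442, and 0.892 with an estimated correlation). In cortex the list test also placed myelin and choroid plexus genes lower and neurofilament genes higher (adjusted p = 0.00437, 0.00529 and 0.0332, and 0.975 in each with an estimated correlation), with 0 members called. In striatum it placed respiratory chain, mitochondrially encoded, choroid plexus and immature neuron genes lower and neurofilament genes higher (adjusted p = 0.000115, 0.0336, 0.0112, 0.0221 and 0.00478, and 0.975 in each with an estimated correlation). There 2 of 37, 0 of 7, 0 of 15 and 2 of 20 were lower and 1 of 22 higher (5, 0, 0, 2 and 1 adjusted over the list alone).

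Between the wild types 56 genes were higher in WTa and 105 lower in cortex, and 490 and 556 in striatum. With the 3 libraries that stand apart left out, none of them wild type, the counts were 472 and 629 in cortex and 849 and 954 in striatum. The cortex total of 161 became 538 without cortex MctOatp KO 1 and 293 without the library labelled cortex MctOatp KO 7. The striatum total of 1046 became 1803 without the library labelled striatum MctOatp KO 7.

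Direct comparison of MctDio KO with MMI asked which genes respond differently when serum hormone is low throughout or in a knockout line without local T3 production by Dio2. Aldh1a1 was higher in MctDio KO by 3.75 ± 0.11 in cortex (adjusted p = 4.76e-24) and by 3.44 ± 0.10 in striatum (adjusted p = 1.25e-24). Kcng4 was higher in cortex (1.82 ± 0.20, adjusted p = 2.05e-07) and Prlr in striatum, at 24.1 ± 19.3 against 1.22 ± 0.665 CPM (4.25 ± 0.55, adjusted p = 3.14e-06, 6 of 7 libraries). Other genes named by the rule were the targeted Dio2 (-5.69 ± 0.14 in cortex) and the copies Rps3a1 and Rps3a3. In cortex 176 genes were higher in MctDio KO and 340 lower, and in striatum 647 and 565. These became 936 and 869 in cortex and 1110 and 897 in striatum without the 3 libraries that stand apart. The cortex total of 516 became 1090 without cortex MctOatp KO 1. The striatum total of 1212 became 2007 without the library labelled striatum MctOatp KO 7.

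The change in MctOatp KO was also compared with the changes in the other models, each taken against its own controls. Relative to MMI, Ly75 and Slco2a1 lay lower in cortex, at -2.35 ± 0.28 and -2.23 ± 0.33 (adjusted p = 4.88e-06 and 0.00012), and in striatum, at -2.10 ± 0.30 and -3.46 ± 0.47 (adjusted p = 5.61e-05 and 3.04e-05). Nr4a1 and Fos, immediate early genes, lay higher by 1.78 ± 0.39 and 1.68 ± 0.44 in striatum, and Adamtsl4 by 1.71 ± 0.25. There Nr4a1 and Fos were lower in WTa than in WT, at -1.24 ± 0.28 and -1.23 ± 0.32 (adjusted p = 0.00548 and 0.0169). In cortex Folr1 (3.95 ± 0.94), F5 (3.62 ± 0.81) and Scn4b (3.99 ± 1.02) lay higher as labelled, and without the 3 libraries Scn4b measured 1.45 (adjusted p = 0.281). Relative to MctDio KO, Aldh1a1 lay lower by -2.72 ± 0.14 in cortex and -2.46 ± 0.13 in striatum (adjusted p = 3.28e-16 and 6.86e-17), and Dio2 higher by 4.99 ± 0.17 and 5.09 ± 0.20. Rtp1 lay lower in cortex (-1.87 ± 0.45), Etnppl lower in striatum (-1.96 ± 0.47), Opalin higher in cortex (1.48 ± 0.33, and 0.87 without the 3 libraries) and Emx2os higher in striatum (1.41 ± 0.26). The difference from MMI gave 59 genes higher and 107 lower in cortex and 286 and 275 in striatum, and that from MctDio KO gave 49 and 83, and 69 and 116. Leaving out the 3 libraries gave 237 and 293, 637 and 455, 109 and 177, and 304 and 260. Without cortex MctOatp KO 1 alone the cortex totals of 166 and 132 became 323 and 219. Without the library labelled cortex MctOatp KO 7 the former became 260. Without the library labelled striatum MctOatp KO 7 the striatum totals of 561 and 185 became 1092 and 564.

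Nearly all genes called in more than 1 model moved the same way. In cortex, MMI and MctDio KO shared 472 genes that were higher in both and 570 lower in both, against 59.4 and 66 expected from independent calls, and 10 moved in opposite directions. In striatum they shared 915 and 1106, against 184.1 and 214.6 expected, with 15 opposite. Across genes the changes correlated at r = 0.727 in cortex and 0.73 in striatum, with covariances of 0.086 and 0.0967. Since both comparisons use the same WT libraries, part of this is built in: unchanged groups simulated against those libraries gave a median r of 0.506 and 0.512, covariances of 0.0108 and 0.0118, and 0 shared calls. The covariance above the simulated value was 0.0752 and 0.0849. With the WT libraries split between the comparisons, medians of 428.5 and 1000 genes were shared in the same direction, with r at 0.574 and 0.62. MctOatp KO has controls of its own. It shared 1192 same-direction genes with MMI in cortex, 538 higher and 654 lower against 123.9 and 92.3 expected, with r at 0.461. In striatum it shared 2217, 1044 higher and 1173 lower against 291 and 293.8 expected, with r at 0.661. With MctDio KO it shared 598 and 1418, with r at 0.347 and 0.594. Genes that moved in opposite directions numbered 18 in cortex and 40 in striatum with MMI, and 15 and 23 with MctDio KO. Over genes called in MMI, the median ratio of the change to that in MMI was 0.619 and 0.591 in MctDio KO, 0.53 and 0.534 in MctDio KO with the WT libraries split, and 0.519 and 0.559 in MctOatp KO. Selecting genes by their calls in MMI lowers these ratios, and selecting them in the knockout raises them: over genes called in the knockout they were 0.848 and 0.872 in MctDio KO and 1.09 and 1.01 in MctOatp KO. Without the 3 libraries that stand apart these became 0.835 and 0.881 in MctDio KO and 0.908 and 0.993 in MctOatp KO. Over genes called in MctOatp KO, whose libraries enter neither other comparison, and without the targeted genes, the mean change in MctDio KO was 0.625 and 0.715 of that in MMI, and 0.666 and 0.671 without the 3 libraries. In cortex the shared counts were 3100, 2666 and 1898 without the 3 libraries that stand apart. There r was 0.607 between MMI and MctOatp KO and 0.503 between the knockouts. In striatum the shared counts were 2847, 2690 and 1864 without them, with r at 0.653 and 0.537 for the same pairs. Genes are not independent replicates, so no p is attached to these correlations.

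**Figure D5:**
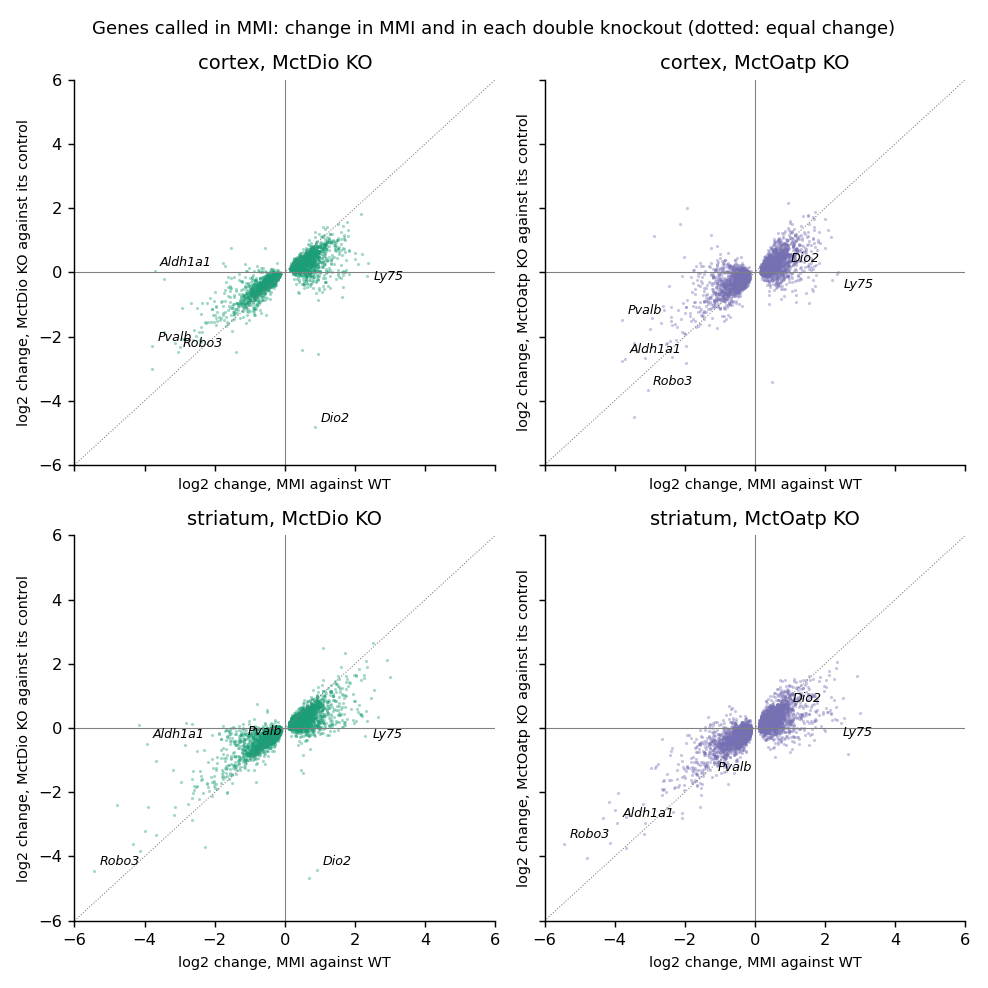
Log2 change in each knockout against its control (vertical axes) by log2 change in MMI against WT (horizontal axes) for genes called in MMI (points), by tissue, with a dotted line of equal change. The median ratio to the change in MMI in cortex is 0.619 for MctDio KO, or 0.53 with the shared WT libraries split, and 0.519 for MctOatp KO, ratios that selecting genes by their calls in MMI lowers, and Aldh1a1 lies near 0 for MctDio KO alone.

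The tissues were compared by testing the change in striatum minus the change in cortex. In MMI, the striatal change lay above the cortical one for Cyp26b1, a retinoic acid hydroxylase (2.60 ± 0.38, adjusted p = 1.74e-06), which rose by 1.70 ± 0.34 in striatum and fell by 0.89 ± 0.19 in cortex, and for Pvalb (2.58 ± 0.42) and Syt2 (2.48 ± 0.34). It lay below for Slc22a3, an organic cation transporter (-3.11 ± 0.26), Nts, the neurotensin gene (-2.82 ± 0.44), and Cnr1, the cannabinoid receptor gene (-2.55 ± 0.16, adjusted p = 3.09e-20). In MctDio KO, Tspan11 (2.01 ± 0.46), Pvalb (1.91 ± 0.40) and Syt2 (1.82 ± 0.33) lay above, and Slc22a3 (-2.63 ± 0.26), Cnr1 (-2.28 ± 0.16) and Nts (-1.76 ± 0.43) below. In MctOatp KO, Nts lay below (-3.13 ± 0.43, and -2.73 without the 3 libraries that stand apart). The other 5 genes of that comparison, Adam33, Hkdc1, Tmem215, Serpina9 and Isl1, passed as labelled but not without those libraries. A tissue difference was called for 172 genes above and 246 below in MMI, for 81 and 107 in MctDio KO and for 255 and 314 in MctOatp KO. The main fit treated the tissues of an animal as independent. With the animal as a block the totals of 418, 188 and 569 became 380, 160 and 337. The block kept 77.3%, 73.9% and 51.3% of the calls. Without the 3 libraries the totals were 1310, 694 and 503. Without cortex MctOatp KO 1 they were 630 for MMI and 287 for MctDio KO. For MctOatp KO, leaving out the library labelled cortex or striatum MctOatp KO 7 gave 342 or 324.

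Knockout lines can carry chromosome segments of another strain near a targeted gene. Genes within 10 Mb of Dio2 or Slco1c1 showed no excess of calls that passed, with adjusted p of 0.956 or more in each test, with or without the 3 libraries that stand apart. In the scan 1 of 2120 tests passed, with p adjusted within each comparison and tissue. In cortex of MMI, 52 of 141 genes between 70000001 and 80000000 on chromosome 15 were called (odds ratio 2.24, adjusted p = 0.00206).

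The remaining lists gave mixed or small changes. In cortex, MMI had 6 genes of thyroid hormone transport, metabolism and receptors higher and 3 lower of 22 (8 and 4 adjusted over the list alone; adjusted p = 0.619), among them Slc7a5, an amino acid and thyroid hormone transporter (0.65 ± 0.10), and Thra, a hormone receptor gene (0.58 ± 0.09). The list was called lower in both tissues of MctDio KO and in cortex of MctOatp KO (adjusted p = 0.00828, 0.00629 and 0.00681, and 0.331, 0.121 and 0.311 with an estimated correlation), where it holds targeted genes. Clock genes were mixed in every main comparison (adjusted p of 0.687 or more), with Hlf at -0.46 ± 0.07 and Per2 at 0.75 ± 0.17 in cortex of MMI. Interneuron markers were not called as a list (adjusted p from 0.113 to 0.954), although Lhx6 and Calb1 rose in striatum of MctOatp KO (0.35 ± 0.08 and 0.68 ± 0.13). Retinoid genes had no call as a list (adjusted p of 0.376 or more), with Crabp2, a retinoic acid carrier, at -1.79 ± 0.32 in striatum of MMI. Glycolysis genes had none either (adjusted p of 0.336 or more): 7 of 23 were higher and 11 lower in striatum of MMI (8 and 11 adjusted over the list alone), with Ldhb at -0.41 ± 0.04. Cortical excitatory neuron markers (adjusted p of 0.101 or more) included Lamp5, which fell by 1.18 ± 0.11 in cortex of MMI, and cholinergic markers had no call as a list (0.0873 or more). Of the cholinergic genes 4 of 7 were higher in cortex of MctOatp KO as labelled and 1 of 9 in striatum of MMI (5 and 0 adjusted over the list alone), and without the 3 libraries that stand apart 0 of 7 were higher in the former. Markers of thalamus, hippocampus and septum (adjusted p of 0.0695 or more) included Wfs1, which rose by 0.83 ± 0.14 in striatum of MMI. Of the sex-linked transcripts none was called in the 6 main comparisons (0 of 4 adjusted over the list alone; adjusted p of 0.318 or more). Over all libraries Xist reached at most 0.555 CPM and Ddx3y at least 44.3 CPM, values of male tissue. Of the lists called in 1 model and not in another, none was tested for a difference between models. Lists called in 1 tissue and not in the other were not tested for a difference between tissues.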

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

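The tests chosen only after the result was seen were the 3 on the libraries labelled MctOatp KO 7, those on other settings and on summed counts for Rps3a1 and Rps3a3, the 3 on the wild-type groups, and the other splits of the samples for MMI in cortex and for MMI in the tissue difference. The 3 patterns weighed first were also chosen after the data were examined. The libraries labelled cortex and striatum MctOatp KO 7 carried the markers of the other tissue. Over 431 genes that differ at least 4-fold between the tissues, the library labelled cortex lay at 0.9301 between cortex (0) and striatum (1), where the other striatum libraries ran from 0.8091 to 1.0943. The library labelled striatum lay at -0.0524, where the other cortex libraries ran from -0.1343 to 0.1246. Neither lay between the tissues, which argues against a mixture of their RNA, and a median of 0.0145 for the other 6 cortex libraries of MctOatp KO argues against an altered regional identity in the double knockout as a group. The values are those that an exchange of the tissue labels of these 2 libraries would give, which stays a hypothesis. Each library lay inside the range of the other tissue, over genes chosen in control libraries. For these 2 libraries that argues against a biological difference of the animal or animals sampled.

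In MctDio KO, counts of Rps3a1 nearly vanished and those of Rps3a3 rose in both tissues. Of 903 windows of 75 nt in the Rps3a1 transcript, 231 were identical in the Rps3a3 transcript and 490 (54.3%) matched it with 1 or 2 mismatches, so a sequence variant in this line may have moved reads from one copy to the other. Alignment or counting with other settings would alter many genes, whereas 1 other gene, Gm5148, changed at least 16-fold the same way in both tissues with no overlap of the groups. In a single tissue, chance separates 7 libraries from 7 others for 0.0583% of genes. Summed CPM of Rps3a1, Rps3a2 and Rps3a3, with TMM factors over all 70 libraries, was 38.7 ± 3.96 against 25.1 ± 1.71 in WT in cortex (ratio 1.54) and 40.1 ± 4.74 against 26.9 ± 4.26 in striatum (ratio 1.49, SD, n = 7). These sums miss reads that match more than 1 copy, so lower expression of ribosomal protein S3a cannot be told apart from divided reads, and this reading of the sums was adopted after they had been seen.

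Genes also differed between the wild-type groups. With TMM factors over all 70 libraries, Wdfy1 and Nnt were higher in WTa and MctOatp KO than in every library of the other 3 groups for 55 of 56 library values, with Nnt in a cortex library at 20.8 CPM against up to 21.1 CPM. With TMM factors within each tissue, computed after that result had been seen, 56 of 56 were higher, and a sequence difference between the mouse lines cannot be told apart from a change in expression for these genes. For glucocorticoid responsive genes, MctOatp KO exceeded WT by 12.8% of the difference between WTa and WT in cortex and by 15.1% in striatum, which settles neither a difference between the lines nor its absence. Of the other 4 groups, 0 had a lower mean of immediate early genes than WTa in either tissue (5.17 ± 0.18 log2 CPM in WTa and 5.86 ± 0.33 in WT in cortex, SD, n = 7). Less neuronal activity at death in WTa animals would give this. The list had already been seen lower in WTa than in WT and MctOatp KO, so the test lends that reading little weight. Other biological differences between these groups, such as their parents, stay open, untested.

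Over 13 measures and 130 groups of 7 libraries, 12 values lay far from the other 6 of their group, and chance alone does this in about 1 in 20 groups. In the library labelled cortex MctOatp KO 1, reads outside genes made up 5.36% (9.21% to 11.66% in the other 6), ambiguous reads 1.9% (1.54% to 1.68%) and alignments that were not unique 39.68% (27.81% to 28.96%). Alignments that were not unique made up 30.47% in cortex MctDio KO 1 (27.88% to 28.75%) and 31.76% in striatum MctDio KO 1 (28.17% to 29.19%), where mitochondrial transcripts took 6.72% of gene reads (4.37% to 4.95%). Number 1 also had the highest share of alignments that were not unique in WT (30.48% in cortex and 30.14% in striatum). The same held in MMI (29.52% and 30.02%), though these values did not lie far from the rest by the same rule. Dio3 stood at 3.702 CPM in cortex MMI 5 (0.2203 to 1.711) and at 2.38 CPM in the library labelled striatum MctOatp KO 7 (0 to 0.2392). The mean of medium spiny neuron genes was 7.957 log2 CPM in the library labelled cortex MctOatp KO 7 (3.883 to 4.919) and 3.818 in that labelled striatum MctOatp KO 7 (8.16 to 8.287). The mean of cortical excitatory neuron genes was 6.308 log2 CPM in cortex WTa 4 (6.359 to 6.396) and 4.739 in the library labelled cortex MctOatp KO 7 (6.093 to 6.447).

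A test of the change in striatum minus the change in cortex singled out 418 genes in MMI, 188 in MctDio KO and 569 in MctOatp KO. Without cortex MctOatp KO 1 these were 630 for MMI and 287 for MctDio KO, and for MctOatp KO they were 342 and 324 without the libraries labelled cortex and striatum MctOatp KO 7. In MMI the difference was 2.60 for Cyp26b1, 2.58 for Pvalb, 2.48 for Syt2, -3.11 for Slc22a3, -2.82 for Nts and -2.55 for Cnr1 (log2). In MctDio KO it was 2.01 for Tspan11, 1.91 for Pvalb, 1.82 for Syt2, -2.63 for Slc22a3, -2.28 for Cnr1 and -1.76 for Nts. In MctOatp KO as labelled it was 3.20 for Adam33, 2.33 for Hkdc1, 2.21 for Tmem215, -3.67 for Serpina9, -3.27 for Isl1 and -3.13 for Nts. Without the 3 libraries that stand apart these became 1.27, -0.062, 0.62, -0.37, -0.43 and -2.73, in that order. Only Nts still passed.

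Other splits of the same samples were tried for each count of called genes, 75 per comparison within a tissue and 35 per tissue difference with the real split included, fewer than 100 to limit computing time. In each of the 17 cases only the real split gave as many genes. The smallest share that could be reached was 1 in 75, or 1 in 35 for a tissue difference. The 17 cases were not adjusted together. Splits that mix differing groups also have a wider spread within groups, which favours the real split. Chance is therefore less likely but not excluded. All libraries entered these splits as labelled. In cortex the real count and the highest of the other splits were 3350 and 1565 for MMI, 1221 and 62 for MctDio KO, 2080 and 324 for MctOatp KO, 161 and 1 for WTa against WT, and 516 and 16 for MctDio KO against MMI. For the change in MctOatp KO they were 166 and 0 when compared with MMI and 132 and 29 when compared with MctDio KO. In striatum the highest of the other splits gave 2152 against 5338 for MMI, 264 against 3566 for MctOatp KO, 22 against 1046 for WTa against WT, and 50 against 1212 for MctDio KO against MMI. For MctDio KO it gave 1601, and the real split gave 1151 genes higher and 1276 lower. For the change in MctOatp KO it gave 26 against 561 when compared with MMI and 7 against 185 when compared with MctDio KO. For the tissue differences the real and the highest other count were 418 and 36 in MMI, 188 and 0 in MctDio KO, and 569 and 184 in MctOatp KO.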

How the results depend on the processing

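The tests chosen only after the data were examined were those without the 3 libraries that stand apart, together or in turn, and those with a block and without the 3. With the settings chosen beforehand, 65 of 112 counts of called genes stayed within 1.5 times the main count and 47 moved. Of 396 list tests 279 were unchanged, 106 lost the call and 11 gained it. Of 5400 tests of named genes 5016 were unchanged, 234 lost the call, 145 gained it and 5 reversed. All 24 window tests near Dio2 and Slco1c1 were unchanged, and all 8 overlap counts moved. With the settings added later included, 82 of 162 counts, 459 of 594 list tests, 7131 of 7744 gene tests, 3 of 14 overlaps and 36 of 36 window tests were unchanged. For the moves below the cause was not tested, except that a fold threshold removes genes by construction.

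Comparisons are given in the order MMI, MctDio KO and MctOatp KO against their controls, WTa against WT, MctDio KO against MMI, and the difference of MctOatp KO from MMI and from MctDio KO. The main totals in that order were 3350, 1221, 2080, 161, 516, 166 and 132 in cortex. In striatum they were 5338 for MMI, the sum of 1151 higher and 1276 lower for MctDio KO, then 3566, 1046, 1212, 561 and 185. Requiring a change of at least 1.5-fold left 1282, 488, 850, 94 and 287 for the first 5 in cortex and 1458, 606, 915, 242, 384, 246 and 114 in striatum. The tissue differences became 264 for MMI and 325 for MctOatp KO under it. Overlaps between models under it were 392 for MMI with MctDio KO, 390 for MMI with MctOatp KO and 208 for both knockouts in cortex, and 495, 511 and 328 in striatum. With the WT libraries split, which leaves fewer of them to each comparison, the overlap of MMI with MctDio KO was 428.5 in cortex and 1000 in striatum.

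Limma voom with quality weights, which gives less weight to variable libraries, gave 6967, 3310, 4946, 1372, 2028, 1531 and 631 in cortex. In striatum it gave 2131 for WTa against WT, 2326 for MctDio KO against MMI, and 1937 and 805 for the differences of MctOatp KO. Its tissue differences were 1613, 586 and 1034. Fitting only the 2 groups compared gave 6274, 2810, 580, 1094 and 1411 for the first 5 comparisons in cortex and 1864 for WTa against WT in striatum. With the number in the title as a block, cortex gave 795 for MctDio KO, 76 for WTa against WT, and 88 and 77 for the differences of MctOatp KO. The same block gave 651 for WTa against WT and 318 and 115 for the differences in striatum. For the tissue differences the block was the animal, read from condition and number, and it gave 337 for MctOatp KO. The DESeq2 Wald test gave 331 for WTa against WT and 388 and 215 for the differences in cortex, and 281 for the difference from MctDio KO in striatum. With no filter on low counts the tissue difference of MctOatp KO was 345. DESeq2 size factors moved no count, and the median change over all genes shifted by at most 0.0039 in size between the scalings.

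Without the 3 libraries, cortex gave 6559, 3760, 3569, 1101, 1805, 530 and 286. Striatum gave 1803 for WTa against WT, 2007 for MctDio KO against MMI, and 1092 and 564 for the differences of MctOatp KO. The tissue differences became 1310 for MMI and 694 for MctDio KO, and 1851 and 1044 with a block as well. The overlaps in cortex became 3100, 2666 and 1898.

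With the libraries labelled cortex MctOatp KO 1 and cortex MctOatp KO 7 left out in turn, cortex gave 4147 to 5463, 1914 to 2610, 2481 to 3160, 293 to 538, 753 to 1090, 260 to 323 and 159 to 219, the higher value each time without cortex MctOatp KO 1. Without the library labelled striatum MctOatp KO 7, striatum gave 6325, 3528, 4098, 1803, 2007, 1092 and 564. With these 3 left out in turn, the tissue differences ranged from 528 to 630 for MMI, from 233 to 287 for MctDio KO, both highest without cortex MctOatp KO 1, and from 324 to 657 for MctOatp KO. The lowest of these was without striatum MctOatp KO 7, and without cortex MctOatp KO 7 it was 342.

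Reversed signs were confined to MctOatp KO in the settings tried. In cortex, without the 3 libraries and with quality weights, the myelin genes Trf (-0.50 and -0.43) and Ermn (-0.46 and -0.37) reversed. So did the globin genes Hba-a2 (-0.73 and -0.64) and Hba-a1 (-0.79 and -0.69) and the respiratory chain gene Ndufa2 (-0.24 and -0.23). Ermn also reversed without cortex MctOatp KO 7 (-0.45, against 0.37 without cortex MctOatp KO 1) and Ndufa2 without cortex MctOatp KO 1 (-0.23, against 0.82 without cortex MctOatp KO 7). Hkdc1 reversed in the tissue difference without the 3 libraries (-0.062). The medium spiny neuron and ribosomal protein lists reversed in cortex without the 3 libraries (adjusted p = 0.626 and 0.985).

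Across list tests, estimating the correlation ended the call for 79 of 198 and left 119 unchanged. Fry ended 27 calls and added 11. Leaving out the 3 libraries ended 5, added 11 and reversed 2. In the tests on simulated counts 28% of genes with the smallest simulated change were called in cortex and 32% in striatum. The raw p needed for a call depends on how many genes change, and far fewer changed there than were called in MMI. These shares therefore cannot tell how often changes of that size were missed in the real comparisons.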
